A study of Arabidopsis thaliana with 2 samples.

How the data were processed

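Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where SOG1 binds in the Arabidopsis thaliana genome. SOG1 (SUPPRESSOR OF GAMMA RESPONSE 1) is a NAC transcription factor that acts in the DNA damage response of plants. Per the labels, plants were 2 weeks old and grown in liquid medium, and whole plants were collected. The ChIP library came from wild-type Col-0 plants carrying SOG1 fused to a Myc tag under the SOG1 promoter, treated for 2 h with 15 µM zeocin, a drug that breaks DNA. The other library came from untagged Col-0 plants labelled mock, precipitated with the same anti-Myc antibody. The treatment text attached to both samples speaks of zeocin, whereas the treatment label of the untagged sample says mock; the label was followed. Each group has 1 library, so there are 2 samples in all and no replicate.

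The analysis used 1 deposited peak list, that of the tagged library after zeocin. Values of the untagged mock library were not analysed here. The submitters' processing notes name CASAVA 1.8.2 and the TAIR10 build, and positions are given as in the peak list, on TAIR10. The read aligner, the peak caller, its control and its thresholds are not given in the sources used here. Peaks were listed for the tagged library alone, and the role of the untagged library in the calling is likewise not given. Per the file headers, the authors list for each peak a count of reads, a fold enrichment (a ratio whose denominator is not stated), a Decibel Score (a score of unstated formula) and a false discovery rate (FDR, a column on the scale of a q-value). The read count per peak is as deposited and not scaled. These are the authors' own values. The fold enrichment, score and read count were used only to describe, rank and select peaks within this list, and no peak was selected by its FDR. The title of the deposited list carries a tag of 5 kb, but the rule by which the authors assigned genes to peaks is not given in the sources used here. The list has 1 line per peak and gene, 1645 lines in all, which were collapsed to 778 peaks by chromosome, start and end. The stated length equals end minus start plus 1 for 517 peaks and end minus start for 261, so edges are uncertain by 1 bp.

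The total depth of either library is not known, so no depth-based interval could be given for a peak. The only counts are the reads inside peaks, 78249 in all. With a single library, a peak's value has no replicate error, and every test describes this peak list and not a difference between conditions.

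No genome sequence or annotation of the build was used here. A gene table of assembly TAIR10.1 served only for gene names, gene classes and the order of neighbouring genes, and none of its positions is printed. Of 1513 gene identifiers named in the peak list, 1483 (98.0%) were matched to it by locus tag and 30 were not. Gene symbols are those in common use for the listed loci, with the locus given once. The authors' list calls AT4G02390 ATPARP1 and AT2G31320 PARP2, the reverse of the symbols used here, which are those of the gene table. Because no strand, exon or sequence of the build was used, the planned tests of peaks near gene starts, of the CTT(N)7AAG site in peaks, of its spacing and of its relation to peak strength were not run, and no peak is described as exonic, intronic or upstream.

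Before the data were examined, 147 genes were placed in 9 lists from general knowledge of the pathway, which includes earlier work on SOG1. The lists are therefore not independent of what was already known of this factor. The planned test, which assigned genes by position, was replaced as foreseen by the genes that the authors name for each peak. Members of each list named for a peak were compared with all 37899 nuclear loci of the table by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 9 lists and a threshold of 0.05. The same test against the 27444 protein-coding loci is given beside it. All list members are protein-coding, and 4.99% of protein-coding loci were named against 3.91% of all loci. The odds ratios against all loci are therefore raised, and those against protein-coding loci are the closer comparison. Shares carry exact 95% binomial intervals (Clopper-Pearson), which cover counting error only. For peak strength, a list's median fold enrichment was given as a percentile among 10000 random lists of the same size drawn from the named genes. Peaks were also placed at random 10000 times along the gene order of their chromosome, keeping the number and spacing of the genes each one names. This gave a one-sided permutation p, of which the smallest possible is 1e-04. Unlike the planned placements by position, neither Fisher's test nor the gene-order placement allows for long genes being hit more often by chance.

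Genes named in the text followed a rule fixed beforehand. It takes the 10 strongest peaks by fold enrichment with all their genes, then members of the damage, kinase inhibitor and transcription factor lists that were named for a peak. It adds SOG1 itself and up to 5 of the strongest members of each other list, and up to 4 members without a peak per list, in list order. Some genes that the rule takes are not reported here. Other genes are said to be chosen afterwards where they appear. The list test against protein-coding genes was tested on simulated data. In 200 random placements of the peaks along the order of the 27444 protein-coding genes, 3 of 1800 list tests gave a call (0.167%). A list of the 28 recombination and repair genes with 25% of its members planted was called in 100 of 100 placements. This is the largest damage list, and the planted share equals the one observed for it. Smaller lists were not planted, so the power of the test for them is not known. The test against all loci was not simulated. Alternatives fixed beforehand were the stronger 50% of peaks, merging of touching peaks and the protein-coding background. Others, chosen after seeing the data, were random placement, peaks naming a single gene, the strongest 25% of peaks, and ranking by Decibel Score or reads. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.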

Results

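The data are a list of 778 peaks that the authors called from 1 anti-Myc ChIP-seq library of whole Arabidopsis plants carrying SOG1-Myc and treated with 15 µM zeocin for 2 h. The series asks which genes SOG1 binds after DNA damage. The fold enrichment, read count and score of each peak are the authors' values, and there is no replicate library.

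Peaks lay on all 5 chromosomes, with 197 on chromosome 1, 115 on chromosome 2, 153 on chromosome 3, 118 on chromosome 4 and 195 on chromosome 5. This followed the number of protein-coding genes, at 26.6 to 30.8 peaks per 1000 such genes (chi-square 1.98 with 4 degrees of freedom, p = 0.739). In bins of 1 Mb the median was 6 peaks and the highest 17, and 9 of 121 bins held none. The median fold enrichment was 4.33 (range 2.49 to 23.0), 562 peaks lay under 5-fold and 23 reached 10-fold or more. A peak held a median of 75 reads (39 to 572) over a median length of 837 bp (472 to 3767). The authors' FDR was 0.116 at the lowest and 0.147 at the median. It was 0.5 at the peak with the highest fold enrichment. The authors named 1513 genes, among them 1369 protein-coding genes, or 4.99% of that class. A single gene was named for 199 peaks, 2 or more genes for 544 peaks and none for 35, so for most peaks the list does not tell which neighbour is the target.

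DNA repair and damage-response genes were named at the strongest peaks. COM1 (AT3G52115), which acts in the processing of DNA ends at double-strand breaks, was named at the peak with the highest fold enrichment, 23.0-fold with 369 reads at chromosome 3, 19325437 to 19326806. Its neighbours AT3G52110 and AT3G52120 were named for the same peak. BRCA1 (AT4G21070), a repair protein of homologous recombination, was the only gene named at the next peak, 17.8-fold with 298 reads at chromosome 4, 11247595 to 11249051. A weaker peak of 4.07-fold at 11251202 to 11251978 also named BRCA1 alone. ANAC085 (AT5G14490), a NAC transcription factor related to SOG1, had a peak of 17.1-fold at chromosome 5, 4672491 to 4673589, shared with AT5G14495. PARP2 (AT4G02390), a poly(ADP-ribose) polymerase activated by DNA breaks, had one of 17.1-fold at chromosome 4, 1049120 to 1050765, shared with SAG21 (AT4G02380) and AT4G02400.

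XRI1 (AT5G48720), known for its induction by X-rays, was named at a 15.7-fold peak at chromosome 5, 19758429 to 19759761, with AT5G48710 and AT5G48730, and at a neighbouring peak of 5.53-fold. RPA70C (AT5G45400), a large subunit of the single-strand DNA binding protein RPA, was the only gene named at a 14.5-fold peak at chromosome 5, 18397814 to 18399229. It was not on any list, so 4 of the 10 strongest peaks named no list gene. RAD17 (AT5G66130), which loads the checkpoint clamp onto damaged DNA, shared a 13.7-fold peak with AT5G66120 at chromosome 5, 26433459 to 26434678. The other 3 of the 10 strongest peaks lay at chromosome 1, 22293211 to 22294280 (16.3-fold, near DRP4C, DRP4D, VPS34 and AT1G60520), at chromosome 2, 7917002 to 7919947 (16.3-fold, near AT2G18180, AT2G18190 and AT2G18193), and at chromosome 5, 2405292 to 2407943 (15.2-fold, near AT5G07590, AT5G07600, AT5G07610, AT5G07625 and AT5G07630). The highest Decibel Score, 1815, belonged to the peak of TSO2, which ranked 18 by fold enrichment.

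**Figure D1:**
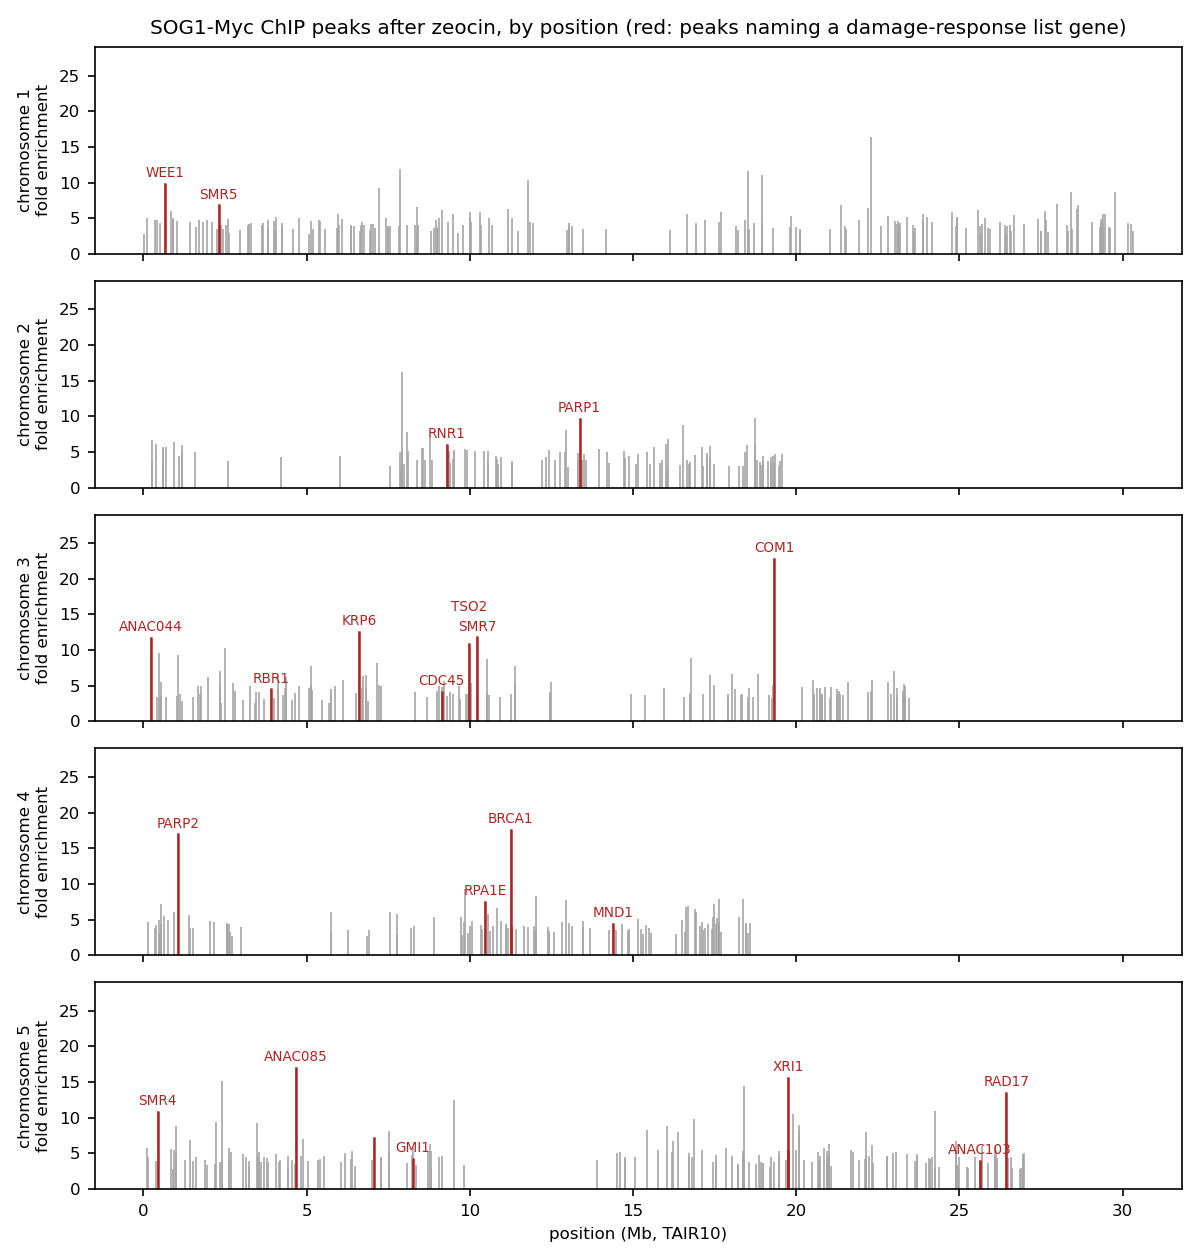
Position of each of the 778 peaks (horizontal axis, Mb on TAIR10) against its fold enrichment (vertical axis), for the 5 chromosomes. Red lines are the 24 peaks that name a gene of the 6 damage-response lists, with the genes given in the text written above their strongest peak, and they include 6 of the 10 tallest.

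Homologous recombination and strand-break repair genes were named more often than other loci. Of 28 listed genes, 7 were named (25%, exact 95% interval 10.7 to 44.9), an odds ratio of 8.22 (Fisher's exact test, adjusted p = 0.000716) against all loci and 6.38 (exact test, adjusted p = 0.0032) against protein-coding genes. Besides COM1, BRCA1 and XRI1, they included RPA1E, another large RPA subunit (AT4G19130; 7.64-fold at chromosome 4, 10468997 to 10469865). MND1, a partner of recombination in meiosis (AT4G29170), had a 4.57-fold peak, and GMI1, a gene induced by gamma rays (AT5G24280), one of 4.39-fold. The peaks of RPA1E, MND1 and GMI1 each named another gene as well. The other 21 members, such as BARD1, were not named.

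Of 9 replication and nucleotide supply genes, 3 were named (33.3%, exact interval 7.49 to 70.1), an odds ratio of 12.3 (Fisher's exact test, adjusted p = 0.00946), or 9.54 against protein-coding genes (exact test, adjusted p = 0.0187). TSO2 (AT3G27060), a small subunit of ribonucleotide reductase, had a peak of 11.1-fold with 572 reads, the highest read count of the list, at chromosome 3, 9979362 to 9981857. RNR1 (AT2G21790), the large subunit of the same enzyme, had one of 6.16-fold at chromosome 2, 9292509 to 9293836. CDC45 (AT3G25100), a factor of the replicative helicase, had a weak peak of 4.25-fold and 43 reads. Each of these 3 peaks named other genes as well. The other 6 members, among them RNR2A, ETG1, MCM2 and MCM5, were not named.

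Inhibitors of cyclin-dependent kinases hold back the cell cycle. Of 16 such genes, 4 were named (25%, exact interval 7.27 to 52.4), an odds ratio of 8.20 (Fisher's exact test, adjusted p = 0.00874), or 6.36 against protein-coding genes (exact test, adjusted p = 0.0187). KRP6 (AT3G19150) had a 12.7-fold peak at chromosome 3, 6615793 to 6618332, and SMR7 (AT3G27630) an 11.9-fold peak at chromosome 3, 10230227 to 10232434. SMR4 (AT5G02220) followed with 11.0-fold at chromosome 5, 441680 to 443316, and SMR5 (AT1G07500) with 6.92-fold at chromosome 1, 2304001 to 2305661. The SMR genes belong to the SIAMESE family, and KRP6 to the Kip-related proteins. Each of these 4 peaks named other genes as well. The other 12 members, such as SIM, SMR1, SMR2 and SMR3, were not named.

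Of 12 transcription factor genes linked to the damage response, 4 were named (33.3%, exact interval 9.92 to 65.1), an odds ratio of 12.3 (Fisher's exact test, adjusted p = 0.00404), or 9.55 against protein-coding genes (exact test, adjusted p = 0.00995). ANAC044 (AT3G01600), a close relative of ANAC085, had an 11.8-fold peak at chromosome 3, 228614 to 229656. The retinoblastoma-related protein gene RBR1 (AT3G12280), a regulator of cell cycle entry, and ANAC103 (AT5G64060), another NAC factor, had weaker peaks of 4.64-fold and 4.09-fold. The peaks of ANAC044, RBR1 and ANAC103 each named other genes as well. ANAC082, MYB3R1, MYB3R3, MYB3R4 and another 4 members were not named.

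The checkpoint and end-joining lists were small and did not pass the test. RAD17 and WEE1 were the 2 of 8 checkpoint genes named (odds ratio 8.19, Fisher's exact test, adjusted p = 0.0549; 6.36 and adjusted p = 0.0855 against protein-coding genes). WEE1 (AT1G02970), a kinase that inhibits cyclin-dependent kinases, had a 9.93-fold peak at chromosome 1, 672560 to 673756, shared with AT1G02960, AT1G02965 and AT1G02980. ATM, ATR, ATRIP and SOG1 (AT1G25580) itself were not named for any peak. In the list of end joining, single-strand break repair and poly(ADP-ribose) polymerases, 2 of 10 genes were named, PARP2 and PARP1 (odds ratio 6.15, Fisher's exact test, adjusted p = 0.0719; 4.77 and adjusted p = 0.11 against protein-coding genes). PARP1 (AT2G31320) had a 9.79-fold peak at chromosome 2, 13359020 to 13361035, shared with AT2G31335 and AT2G31340. KU70, KU80, LIG1 and LIG4 were among the 8 without a peak. Both lists passed among the 389 strongest peaks (exact test, adjusted p = 0.0224 for the checkpoint and 0.0233 for end joining; 0.00786 to 1 over the 7 other settings tried for either).

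**Figure D2:**
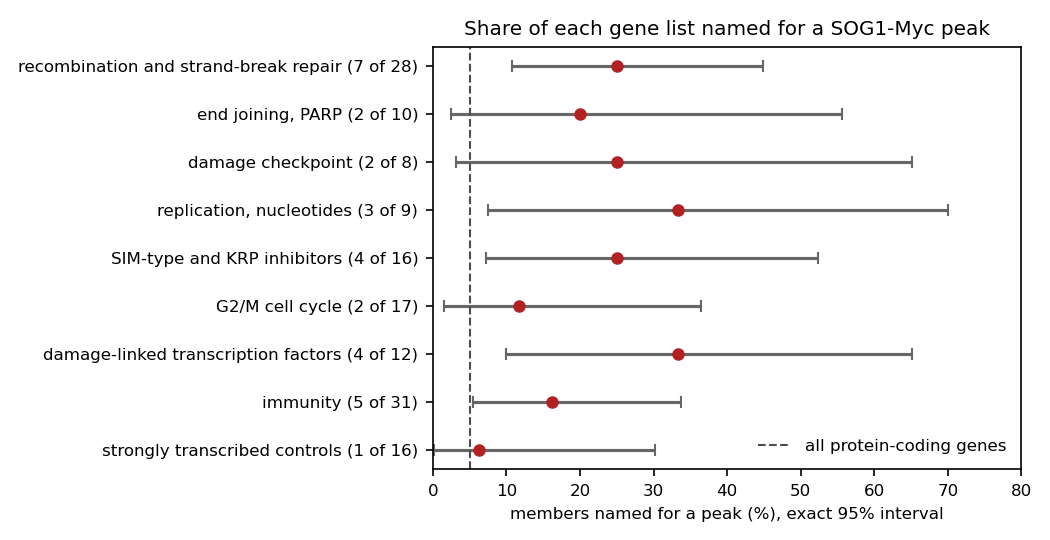
Percent of the members of each of the 9 lists that the authors name for a peak (points), with exact 95% intervals (bars) and the 4.99% of all protein-coding genes (dashed line). The interval lies above the line for recombination and repair, replication, kinase inhibitors, damage-linked transcription factors and immunity.

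Of 17 G2/M cell cycle genes, 2 were named, an odds ratio of 3.28 that did not pass (Fisher's exact test, adjusted p = 0.159), nor did the 2.54 against protein-coding genes (exact test, adjusted p = 0.233). The mitotic cyclin gene CYCB1;1 (AT4G37490) had a 4.70-fold peak and CCS52A1 (AT4G22910), an activator of the anaphase-promoting complex, one of 3.21-fold. CYCB1;2, CYCB2;1, CYCB2;2 and CYCA1;1 were among the 15 without a peak.

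Of 31 immunity genes, 5 were named (16.1%, exact interval 5.45 to 33.7), an odds ratio of 4.73 (Fisher's exact test, adjusted p = 0.0119), or 3.67 against protein-coding genes (exact test, adjusted p = 0.0318). Their peaks were of ordinary strength. The transcription factor genes WRKY25 (AT2G30250), WRKY50 (AT5G26170), WRKY18 (AT4G31800) and WRKY53 (AT4G23810) had 4.95-fold, 4.62-fold, 4.21-fold and 3.91-fold peaks, and PEPR1 (AT1G73080), a receptor of danger peptides, one of 3.25-fold. WRKY33, WRKY40, WRKY46 and WRKY70 were not named. Split after the values were seen, 4 of the 8 WRKY members were named but 1 of the other 23 (4.35%, exact interval 0.11 to 21.9), close to the 4.99% of all protein-coding genes, so the call rests on WRKY genes. Among the 389 strongest peaks the list no longer passed (exact test, adjusted p = 0.158; 0.0119 to 1 over the 7 other settings).

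Of 16 strongly transcribed photosynthesis and housekeeping genes, taken as controls, only the ubiquitin gene UBQ10 (AT4G05320) was named (odds ratio 1.64, Fisher's exact test, adjusted p = 0.472; 1.27 and adjusted p = 0.559 against protein-coding genes). Its peak was wide and weak, 2.71-fold over 3119 bp. ACT2, GAPC1, EF1A and LHCA1 were among the 15 without one.

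The 6 lists of repair, checkpoint, replication, kinase inhibitor and damage-linked transcription factor genes were also pooled, a grouping made after the values were seen. Of 83 genes, 22 were named (26.5%, exact interval 17.4 to 37.3; odds ratio 8.97, Fisher's exact test, p = 6.54e-13). Against protein-coding genes the odds ratio was 6.97 (exact test, p = 7.12e-11). The median fold enrichment of these 22 genes was 10.5, against 4.33 for all 1483 matched genes, and lay above that of all 10000 random lists of 22 named genes. For the immunity genes the median was 4.21, at percentile 42.4 of random lists of its size, and for the G2/M genes, not in the pool, 3.96, at percentile 25.2. Taken singly, the pooled lists stood at percentiles from 94.5 (replication and nucleotide supply, median 6.16) to 99.98 (kinase inhibitors). Peaks of the pooled lists made up 6 of the 10, 12 of the 25 and 17 of the 100 strongest by fold enrichment, out of 24 such peaks in all. By the labels, the tagged, zeocin-treated library differs from the untagged mock library in both genotype and treatment, so these values do not separate the tag from the drug. Restricted to the 199 peaks that name a single gene, none of the 9 lists passed, with at most 1 member of any list named. Of the 22 pooled genes, only BRCA1 was named at such a peak, and each of the others shared its peaks with other named genes.

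**Figure D3:**
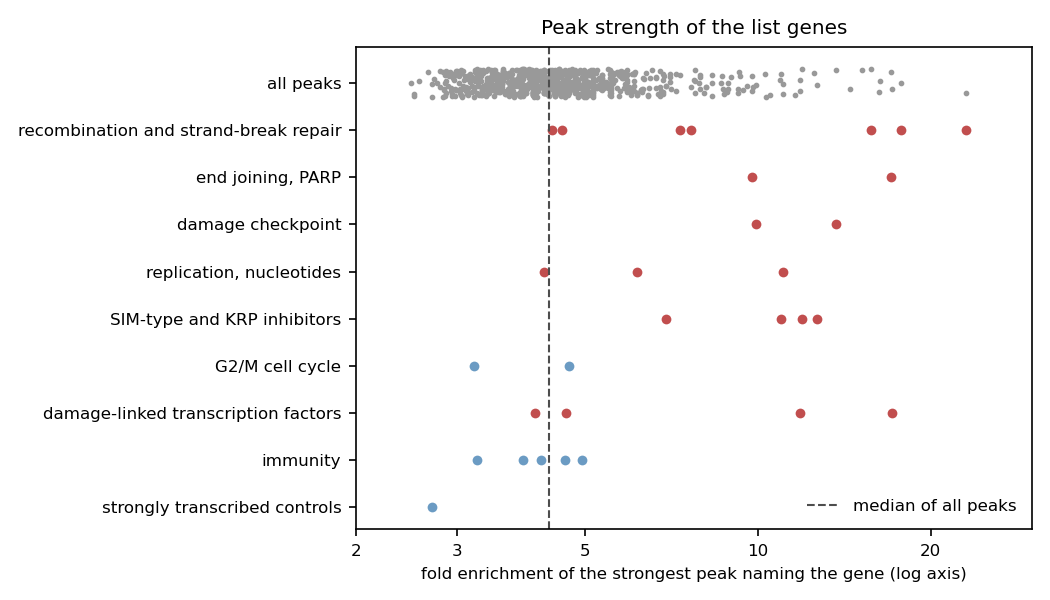
Fold enrichment (horizontal log axis) of all 778 peaks (grey) and of the strongest peak naming each list gene, for the 6 damage-response lists (red) and the other 3 lists (blue). The dashed line is the median of all peaks, 4.33, and 20 of the 22 red genes lie above it.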

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

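The tests in this part were all chosen after the values had been seen. The FDR column, which no comparison above uses, drew attention because it does not fall towards the strongest peaks. It runs from 0.116 to 1, and its highest value belongs to the peak of TSO2 that ranks 1 by Decibel Score. FDR times the rank by Decibel Score is a whole number, within 0.01, for 772 of 778 peaks (99.2%), against 22 peaks when ranked by fold enrichment. This argues against the column being anything other than a running count divided by rank, and a candidate explanation is the number of calls made with ChIP and control exchanged, although no source used here says so. Ranked by this score, the running count is 2 at the 10 strongest peaks, 26 at the 194 strongest and 115 at all 778. It amounts to 13.4% of the 194 strongest peaks and 14.8% of all peaks, which restates the column and does not test whether false calls are weak peaks. That and what the counted regions are stay open, and no biological explanation was tested.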

How the results depend on the processing

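The odds ratios of the 9 lists (for random placement, observed over expected members) were recomputed under 7 other settings; those with peaks naming a single gene, the 194 strongest peaks, the Decibel Score ranking and random placement were chosen after seeing the data. Of 63 such results, 43 kept their direction and their side of the threshold, among them every list under the protein-coding background and under random placement, where recombination and repair genes were 4.77 times the expected number. Merging touching peaks changed nothing by construction, as no peaks touch, so its results for the 9 lists, counted among the 43, were fixed in advance. Among the 389 strongest peaks by fold enrichment, the end-joining and checkpoint lists passed (odds ratios 12.5 and 16.7), immunity no longer passed (3.46) and the controls had an odds ratio of 0. The 389 strongest by Decibel Score gave 12.5, 16.7, 3.45 and 0 for the same lists. Among the 194 strongest peaks, end joining rose to 24.5 and the checkpoint list to 32.7, while G2/M, immunity and control genes were at 0. With the 199 peaks that name a single gene, 0 lists passed against 5; recombination and repair had an odds ratio of 7.50 (exact test, adjusted p = 0.388; 8.06e-06 to 0.388 over all settings), and end joining, checkpoint, replication, kinase inhibitor, transcription factor and immunity genes stood at 0, while G2/M and control genes, with 1 member each, rose to 12.7 and 13.5 without passing (exact test, adjusted p = 0.363 for both; 0.159 to 1 and 0.363 to 1 over the settings). These zeros come with far fewer genes named; the cause was otherwise not tested. The pooled damage genes' median Decibel Score and median read count also lay above those of all 10000 random lists. Not run, for want of a sequence or strand of the build: the gene-start, CTT(N)7AAG, spacing and strength-by-site tests with all their alternatives, and the position windows of the list test. Library depth is not known, so a list gene without a peak cannot be told from one below detection.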

Other observations

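The tests in this part were all chosen after the values had been seen. Genes were also grouped by words in their names into 34 families, and 7 were named more often than other protein-coding genes after adjustment over the 34. Fisher's test counts genes that share a peak as separate members. Random placement along the gene order keeps such genes together, and the same 7 passed there (permutation test, adjusted over the 34 families p = 0.0034 to 0.0481; 0.0314 for ERF and DREB factors). WRKY transcription factors, many of them regulators of defence and stress responses, had the lowest p, with 16 of 71 members named, 4 of them also in the immunity list (22.5%, exact 95% interval 13.5 to 34.0; odds ratio 5.59, Fisher's exact test, adjusted p = 1.09e-05). The strongest were WRKY48 (AT5G49520; 8.34-fold at chromosome 5, 20088158 to 20089707) and WRKY22 (AT4G01250; 7.21-fold at chromosome 4, 525014 to 525740). ERF and DREB factors had 8 of 46 members named, among them DREB19 at 6.85-fold, ERF8 at 5.36-fold and the cold-response genes DREB1A and CBF1 at 1 shared peak of 4.53-fold (odds ratio 4.03, exact test, adjusted p = 0.0153). Basic leucine zipper factors had 9 of 49, including the light regulator HY5 at 3.86-fold and BZIP60 at 3.33-fold (odds ratio 4.31, exact test, adjusted p = 0.00933).

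Genes with calmodulin in their names followed with 8 of 41 members (odds ratio 4.64, exact test, adjusted p = 0.00933), among them CAM4 at 5.93-fold and the touch-induced TCH3 and CAM2 at a shared 3.01-fold peak. The strongest of the 8 was NTL9 at 6.44-fold, and CPK7 was another, so this group by name is not limited to calmodulins. Zinc finger genes had 9 of 69 and telomere-named genes 5 of 25, among them TRFL10 at 8.88-fold and the telomerase gene TERT at 4.63-fold (odds ratios 2.87 and 4.78, both exact adjusted p = 0.0403). RPA genes had 3 of 9, RPA70C, RPA1E and RPA1A (odds ratio 9.54, exact test, adjusted p = 0.0403). NAC factors, the family of SOG1, had 10 of 104 and did not pass (odds ratio 2.03, exact test, adjusted p = 0.169), and ribosomal protein genes had 1 of 70. The NAC group, made by name, missed NTL9, a NAC factor that was counted with the calmodulin names. Genes grouped by DNA repair names had 4 of 30 and did not pass either (odds ratio 2.94, exact test, adjusted p = 0.228). They also did not pass among the 389 strongest peaks (odds ratio 6.01, exact test, adjusted p = 0.0637). Among the 389 strongest peaks WRKY genes still passed, and the other 6 families did not (exact tests, adjusted p = 0.0637 to 0.235). The odds ratios of these 6 were still 3.05 to 11.1 there, with fewer genes named, and only that of calmodulin fell, from 4.64 to 3.08.

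The damage-response genes at the strongest peaks invite technical explanations. Strongly transcribed genes can be recovered in ChIP whatever the antibody binds; 2 of 86 ribosomal protein and control genes were named (2.33%), against 22 of 83 damage-response genes (Fisher's exact test, p = 3.62e-06), but such genes are transcribed with or without zeocin and could cancel against an untagged control, so this leaves the explanation open, above all for genes that zeocin induces. Naming several genes per peak inflates any list, yet random placement of the peaks along the gene order, with the same number of genes per peak, gave on average 4.34 members and at most 15, so the observed number was 5.07 times the expected one. The explanation by zeocin treatment and not the tagged protein cannot be told apart from binding by SOG1. By their labels the libraries differ in 2 attributes at once, genotype and treatment, though the treatment text of both speaks of zeocin. Binding of SOG1 near repair genes may underlie the pattern, as a hypothesis that needs an untagged library known to be treated with zeocin.

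The WRKY genes had a median fold enrichment of 4.59 at the strongest peak of each gene, close to the 4.33 of all peaks, so weak peaks at random positions might produce them. The 389 stronger peaks alone named 10 of them, an odds ratio of 6.45 (exact test, p = 1.07e-05, adjusted over the 34 families 0.000364). Among genes named by the 389 weaker peaks, WRKY genes had an odds ratio of 4.04 (exact test, p = 0.00277, adjusted over the 34 families 0.0470), but the family was picked on these same peaks, so neither value decides whether weaker peaks at random positions give the excess. Random placement of all peaks along the gene order gave on average 3.66 WRKY genes and at most 11. The observed 16 were 4.37 times that average (permutation test, adjusted over the 34 families p = 0.0034). Within this list, this argues against several genes named per peak as the whole cause. The placement went by gene order alone and did not allow for gene length or for the distance between genes. It also used the peaks on which the family was picked. It therefore does not decide whether peaks at random genome positions give the excess. WRKY genes respond to many stresses, and zeocin treatment and not the tagged protein stays open here too, with 2 attributes differing between the libraries by their labels.

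Adjacent peaks were often close together. There were 33 pairs with a gap under 1000 bp, against an average of 10 and at most 20 in 1000 uniform placements that ignored gene density. They include both XRI1 peaks, 566 bp apart, and the peaks of 8.34-fold and 6.75-fold that name WRKY48, 150 bp apart. The 39 peaks longer than 2000 bp held a median of 273 reads at a median of 4.83-fold, against 73 reads and 4.31-fold for the other 739.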
